A study of Drosophila melanogaster with 6 samples.

How the data were processed

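RNA was measured in olfactory projection neurons of Drosophila melanogaster, the cells that carry odour information from the antennal lobe to higher brain centres. Per the labels' protocols, cells carrying a GFP marker were collected by fluorescence-activated sorting, about 2000 cells per library, and libraries were made with SMART-seq2, a full-length cDNA method for small amounts of RNA. Flies were untreated. The series has 6 libraries in 2 groups of 3, one group collected 36 h after puparium formation (development) and one from adults of 5 days (adult). Groups and replicate numbers were taken from the library titles.

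The deposited table holds log2 values, which the values themselves show to be log2(CPM + 1), where CPM is the number of reads of a gene per 1000000 reads assigned to the listed genes: after conversion each library sums to 1000000. STAR 2.4.2a and HTSeq 0.7.1 are named in the submitters' processing notes, without their roles. The genome build, the annotation, any filter and the use of strand are not given in the sources used here. The table has 14139 rows, 1 of them without a symbol. That row took at most 0.0001% of any library and was left out. Another 5 symbols had been turned into dates by a spreadsheet and were kept under those names. Of the 14138 rows used, 14025 were matched to a FlyBase identifier, and coordinates are those of BDGP6.54 in Ensembl release 115. Symbols are printed as the table gives them.

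Low CPM values were whole multiples of a single step per library, so reads could be recovered. Of the values above 0, 100.0% came out whole within a tolerance of 0.1 read. Recovered reads ranged from 18602628 to 42217764 per library. Such reads carry no molecular identifiers, so an interval computed from them covers counting error only. Intervals for ratios resting on 3 reads or fewer are exact binomial ones at 95% confidence.

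Genes with a CPM of at least 5 in at least 3 of the 6 libraries were tested, 6814 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend, two-sided) on log2(CPM + 1), with group as the only term and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. Fold changes are adult minus development on the log2(CPM + 1) scale, with a pseudocount of 1, which understates the change of low genes. In data simulated for this comparison, with 200 changed genes among 6763 tested, the same code recovered 99% of genes changed by 1 log2 unit and 100% of those changed by 2 log2 units, and 6.13% of its calls were false. The simulated changes were balanced up and down, in genes with a mean of at least 20 CPM, at a single assumed dispersion. In the measured data 65.15% of tested genes passed the threshold, so the simulated rates are not those of the calls below.

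Before the data were examined, 36 gene lists were fixed, covering wiring molecules, dpr and DIP genes, beat and side genes, the cytoskeleton of growing neurites, synaptic vesicles and active zones, transmitter identity, transmitter receptors, ion channels, neuropeptides, transcription factors of projection neurons, ecdysone response and temporal regulators, and activity and clock genes. Others covered ribosomes, mitochondrial ribosomes, translation factors, nuclear and mitochondrial genes of oxidative phosphorylation, glycolysis, the proteasome, the vacuolar proton pump, the spliceosome, apoptosis, immune genes, detoxification, heat shock and sex-linked genes. The remaining lists were markers of dividing cells, glia, hemocytes, muscle, photoreceptors, fat body, olfactory receptor neurons, Kenyon cells, other neurons and cuticle. Lists with at least 5 tested members, 34 in all, were tested with camera (limma), which compares a list's genes with all other genes, at a preset inter-gene correlation of 0.01 and, beside it, with an estimated correlation. The summed share of CPM was computed per library for 14 gene classes and compared by an exact two-sided permutation test, for which 3 against 3 libraries cannot give a p below 0.1.

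Genes named in the text follow a rule also fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among genes past the threshold with a mean CPM of at least 20, non-overlapping groups and a symbol other than a CG or CR number or a noncoding RNA name, which passed over 16 rising and 4 falling genes. It adds up to 2 rising and 2 falling members of each list, the most abundant member of each marker list, and a fixed panel of projection neuron, synaptic and temporal genes. Alternatives covered the pseudocount, the filter, the scaling, the replicate number as a block, the variance model, library weights, limma voom on the recovered reads, stricter thresholds, the correlation used by camera, the base of the shares, and leaving out each library in turn. The leave-one-out fits were first run with the filter applied anew to the 5 libraries left, which removes genes found only in the group left with 2 libraries. Holding the 6814 tested genes fixed was chosen after those results had been seen, and both versions are reported. List members were matched to the table by exact symbol, which missed 7 members of 3 lists that differ in letter case, a matter noticed after the results had been seen. These lists were therefore also tested with the 7 members added. Summaries and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.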

Results

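The series asks how the transcriptome of olfactory projection neurons differs between a stage of circuit assembly, 36 h after puparium formation, and the mature adult at 5 days. Each group holds 3 libraries of sorted cells. Recovered reads were 31139403, 34542641 and 18602628 in the development libraries and 42217764, 32764616 and 40668115 in the adult libraries. Between 7813 and 7979 genes reached 1 CPM in each library. Nothing in the labels says whether the 3 libraries of a group came from separate animals or sorts, so p-values measure the spread between these libraries, which may be technical. All pairs of libraries within a group differed by more than counting noise, with a chi-square per degree of freedom of at least 18.12. In development the pairs holding replicate 1 had 74.02 and 60.53, against 18.12 for replicates 2 and 3, and adult pairs had 44.24 to 63.74. Some wide development SDs below rest on replicate 1. Examples are nSyb, at 1734, 1152 and 1010 CPM in replicates 1, 2 and 3, and ND-75, at 305, 167.1 and 170 CPM. The row for the mCD8-GFP marker transgene had 14850 ± 1929 CPM in development and 13550 ± 1013 CPM in adult (SD, n = 3 each) and did not pass the test (limma, adjusted p = 0.3036).

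In adult projection neurons 13 of 14 tested genes of the glycolysis list, 32 of 48 synaptic vesicle and active zone genes and 33 of 45 ion channel genes were higher than in developing ones. Lower in adult were 52 of 85 wiring genes, 80 of 82 ribosomal protein genes and all 31 proteasome genes (limma, each gene at an adjusted p under 0.05). Choline acetyltransferase (ChAT), the enzyme that makes acetylcholine, rose from 43.8 ± 8.63 to 569.2 ± 15.41 CPM, and the glycolytic enzyme gene Pfk rose from 33.41 ± 2.719 to 599.1 ± 34.86 CPM (SD, n = 3). The adhesion molecule CadN fell from 529.6 ± 19.74 to 173.2 ± 15.57 CPM, and the small heat shock gene Hsp67Bc fell from 7506 ± 972.8 to 29.26 ± 3.341 CPM. All 4 genes had an adjusted p of 1.312e-08 or lower (limma).

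Of 6814 genes tested, 4439 (65.15%) changed at an adjusted p under 0.05 (limma), 1856 higher and 2583 lower in adult. At least 2-fold changes numbered 916 higher and 1229 lower, and at least 16-fold changes 53 higher and 20 lower. The 3 libraries of one group lay wholly above those of the other for 4701 genes (68.99%), where chance gives 10%. The median log2 fold change of all tested genes was -0.153, so the balance of rises and falls follows the scaling, and list medians are to be read against that value. With each library's median log ratio set to 0, 2222 genes were higher and 2181 lower. Pearson correlations of log2(CPM + 1) across genes, which are not independent replicates, were 0.977 to 0.99 within groups and 0.784 to 0.803 between them, and the first principal component held 89% of the variance.

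The largest rises among genes named by the fixed rule were led by Gbs-76A (FBgn0036862, 3L, 19281364 to 19292766), a glycogen-binding regulatory subunit gene of protein phosphatase. It went from 0.8132 ± 0.6242 to 218.5 ± 34.63 CPM, a log2 fold change of 6.97 ± 0.259 (SE; limma, adjusted p = 7.45e-11). The other 11 were hoe2, Gad1, Ddc, Gpdh, Rab27, Tektin-C, AcCoAS, Tob, St3, Mef2 and IA-2, with log2 fold changes from 5.53 for hoe2 down to 4.18 for IA-2. AcCoAS, an acetyl-coenzyme A synthetase gene, reached 4378 ± 356 CPM in adult from 209.5 ± 34.08, and IA-2, a dense-core vesicle membrane protein gene, reached 2898 ± 267.6 CPM from 159.2 ± 22.81. The exons of Gpdh overlap an antisense noncoding gene over 22.11% of their length, and the use of strand in the counting is not given in the sources used here.

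The largest falls among genes named by the fixed rule, which passed over 4 falling genes by their symbols, were led by Hsp67Bc (FBgn0001229, 3L, 9371511 to 9372497), with a log2 fold change of -7.95 ± 0.118 (SE; limma, adjusted p = 2.508e-14). Next was the nuclear receptor gene Hr4 (FBgn0264562, X, 1941940 to 2007956), which fell from 713.4 ± 52.58 to 4.111 ± 0.5658 CPM. The channel gene Trpgamma had 3967 recovered reads in development and 1 in adult, a ratio of 5443 after scaling to depth (95% interval 976.4 to 215100). Act42A, a cytoplasmic actin gene, fell from 6983 ± 581 to 213.2 ± 16.34 CPM, although reads that match other actin genes leave its level uncertain. The remaining 8 were Dtg, Myo81F, fabp, stet, nemy, Obp44a, twz and Hsp23, with log2 fold changes from -4.75 for Dtg to -3.77 for Hsp23. Of the exonic bases of fabp, 72.11% also belong to sea on the same strand, so its value is uncertain. The value of Obp44a is uncertain too, since 19.05% of its exonic bases overlap Pabp2 on the opposite strand and the use of strand is not given.

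**Figure D1:**
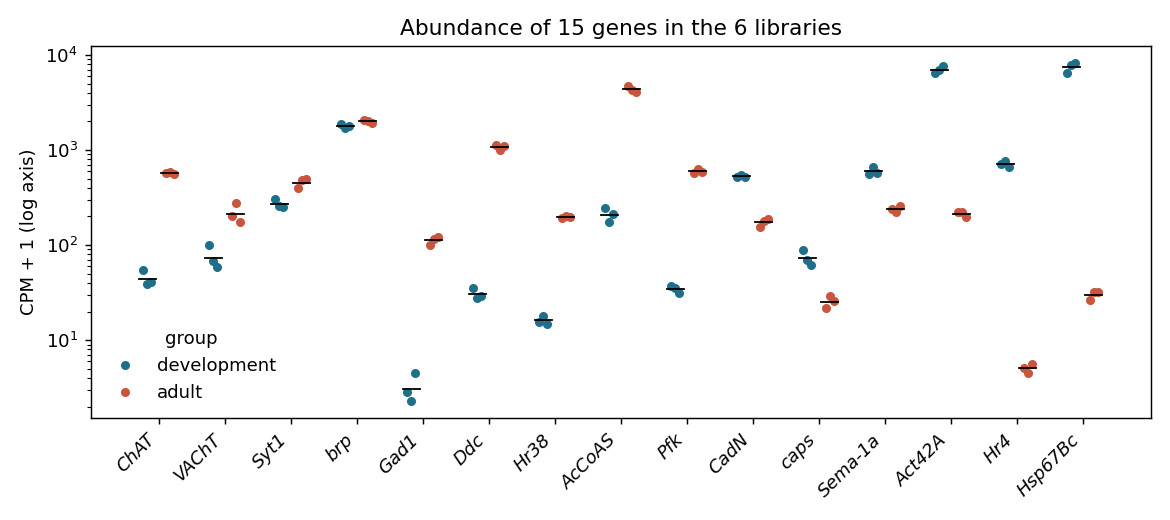
CPM + 1 on a log axis for 15 genes in the 6 libraries, with a point per library and a bar at the geometric mean of each group. The 3 adult points of ChAT, Gad1, Ddc and Pfk lie above all development points, and those of CadN, Act42A, Hr4 and Hsp67Bc lie below.

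For the gene lists, counts adjusted over the list alone equalled those over all genes tested for 31 of 36 lists, and the other 5 are given where they differ. With camera at the preset correlation, 20 of 34 lists passed an adjusted p of 0.05, 13 higher and 7 lower in adult. With an estimated correlation 0 lists passed, 10 had an unadjusted p under 0.05, and the lowest adjusted p was 0.06482. The calls below are therefore those of the preset correlation, and the p with an estimated correlation stands beside each. Estimates ran from -0.104 for sex-linked and yolk genes to 0.764 for mitochondrially encoded genes. They were 0.584 for ribosomal protein genes, 0.465 for nuclear genes of oxidative phosphorylation, 0.164 for proteasome genes and -0.031 for glycolysis genes. Where the estimate lies far above 0.01, the p at the preset correlation overstates the evidence. Lists with an estimate below 0.01 lost their call too. Glycolysis genes went from an adjusted p of 1.008e-10 to 0.06482, and spliceosome genes, with an estimate of -0.008, from 0.0002236 to 0.08086 (camera). A low estimate is therefore no assurance that a call holds.

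Wiring molecules fell as a group: of 85 tested members 52 fell and 7 rose, with a median log2 fold change of -0.64 (camera, adjusted p = 0.0008654; adjusted p = 0.2224 with an estimated correlation). The semaphorin gene Sema-1a, whose product guides projection neuron dendrites, fell by 1.32 ± 0.103 on the log2 scale (SE). The leucine-rich repeat gene caps fell by 1.52 ± 0.176, and otk and Sema-2a fell by 2.5 ± 0.213 and 2.11 ± 0.143. Fas1 and jeb, the ligand gene of the receptor Alk, went the other way, with log2 fold changes of 2.79 ± 0.102 and 2.62 ± 0.1. Ten-a fell by 0.4 ± 0.097, while its relative Ten-m had 219.6 ± 29.21 CPM in development and 227.4 ± 4.726 CPM in adult and did not pass the test (limma, adjusted p = 0.6715). The endocytic receptor gene LRP1 fell by 0.75 ± 0.113. The immunoglobulin families did not pass as lists: 6 of 29 dpr and DIP genes rose and 9 fell, 8 when adjusted over the list alone (camera, adjusted p = 0.85). Likewise 3 of 21 beat and side genes rose and 10 fell (camera, adjusted p = 0.7061). Among them beat-VII rose from 100.4 ± 47.53 to 570 ± 43.94 CPM and DIP-eta fell from 158.3 ± 33.59 to 70.81 ± 6.249 CPM.

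Genes for the cytoskeleton of growing neurites moved both ways, with 27 of 49 lower and 13 higher (camera, adjusted p = 0.04711; adjusted p = 0.1873 with an estimated correlation). The actin-binding protein genes tsr, which encodes cofilin, and cib fell by 3.66 ± 0.103 and 3.76 ± 0.124 on the log2 scale (SE), and the formin genes dia and capu rose by 1.74 ± 0.196 and 1.69 ± 0.215. This call ended without development replicate 1 (adjusted p = 0.06619), without adult replicate 3 (0.05325), and under 3 other settings. With the expression filter applied anew to the libraries left, it ended in 4 of 6 such fits (adjusted p = 0.06504 to 0.08059).

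Synaptic vesicle and active zone genes rose in 32 of 48 cases and fell in 5, with a median log2 fold change of 0.73 (camera, adjusted p = 1.286e-06; adjusted p = 0.1215 with an estimated correlation). With Fife, left out for the letter case of its symbol, 33 of 49 rose (camera, adjusted p = 5.268e-07). The fusion ATPase gene comt rose from 17.2 ± 2.139 to 200.2 ± 6.381 CPM, and nwk from 54.3 ± 3.106 to 413 ± 50.54 CPM. Syt1 rose from 272.6 ± 29.17 to 455.6 ± 53.58 CPM and nSyb from 1299 ± 383.6 to 2218 ± 132.6 CPM. The active zone scaffold gene brp did not pass the test (log2 fold change 0.16 ± 0.083; limma, adjusted p = 0.1). It passed with median of ratios scaling (log2 fold change 0.313, adjusted p = 0.004893), with array weights (adjusted p = 0.02182) and without development replicate 1 (0.01964, or 0.01849 with the filter applied anew), while its log2 fold change was -0.066 with quantile normalization (adjusted p = 0.473, the highest over all settings). RhoGAP100F fell by 1.45 ± 0.105 on the log2 scale.

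Ion channel genes rose in 33 of 45 cases and fell in 4 (median log2 fold change 0.8; camera, adjusted p = 4.959e-08; adjusted p = 0.08086 with an estimated correlation). Left out of these counts were Trpgamma, which fell, and Teh1 to Teh4, whose symbols differ in letter case from the list as fixed. With them 35 of 50 rose and 5 fell (camera, adjusted p = 1.209e-07). Ih, the gene of the hyperpolarization-activated cation channel, rose from 172 ± 10.13 to 1182 ± 77.79 CPM. The potassium-chloride cotransporter gene kcc rose from 34.44 ± 1.476 to 257.6 ± 10.58 CPM. Transmitter receptor genes rose in 21 of 40 cases and fell in 9 (camera, adjusted p = 0.02652; adjusted p = 0.1551 with an estimated correlation), a call that ended with a filter at 20 CPM (adjusted p = 0.05543) and without development replicate 3 when the filter was applied anew (0.05023). The octopamine receptor gene Octbeta1R rose from 248.1 ± 48.17 to 1277 ± 76.87 CPM. Nmdar2 rose by 1.69 ± 0.118 on the log2 scale (SE), and the acetylcholine receptor gene nAChRalpha7 fell from 770.7 ± 18.53 to 315.8 ± 13.71 CPM.

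Transmitter synthesis and vesicular transport genes rose in 12 of 16 cases and fell in 1 (median log2 fold change 1.41; camera, adjusted p = 2.028e-05; adjusted p = 0.2224 with an estimated correlation). VAChT, the vesicular acetylcholine transporter gene, went from 74.27 ± 21.95 to 216.2 ± 52.52 CPM. ChAT lies at 3R, 18705501 to 18732344, and shares 15.11% of its exonic bases with VAChT on the same strand, so reads from that part cannot be assigned to either with certainty. The list also held genes of other transmitters. Gad1, the GABA synthesis enzyme gene, rose from 2.199 ± 1.155 to 111.4 ± 11.72 CPM. Ddc, which encodes dopa decarboxylase, rose from 29.83 ± 4.169 to 1075 ± 71.67 CPM. Tbh, the octopamine synthesis enzyme gene, fell from 396.8 ± 122.3 to 196.4 ± 41.72 CPM. These 3 genes also belong to the marker list of other neurons, of which 6 of 9 tested members rose and 1 fell (camera, adjusted p = 0.01012; adjusted p = 0.2224 with an estimated correlation). This call ended without adult replicate 2 when the filter was applied anew (camera, adjusted p = 0.08145). The share of CPM in that list was 0.0496% ± 0.0143 in development and 0.168% ± 0.0173 in adult (SD, n = 3).

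Neuropeptides, their processing enzymes and receptors rose in 24 of 43 cases and fell in 7 (median log2 fold change 1.06; camera, adjusted p = 0.001874; adjusted p = 0.1551 with an estimated correlation). With the filter applied anew, this call ended without adult replicate 2 (camera, adjusted p = 0.08145) and without adult replicate 3 (0.08571). Precursor genes varied between adult libraries, with an SD at a median percentile of 84 among 50 genes of nearest level (30 genes; permutation p = 1e-05, the smallest that 100000 random lists can give). That p treats the 30 genes as independent, though all were measured in the same 3 libraries and may vary together, so it overstates the evidence. Proc, which encodes proctolin, rose from 8.032 ± 2.627 to 149.5 ± 29.16 CPM, and Dh44 rose from 2.837 ± 1.105 to 41.59 ± 5.111 CPM. The insulin receptor gene InR fell from 113.1 ± 4.665 to 43.92 ± 2.802 CPM. Activity and clock genes rose in 7 of 14 cases and fell in 2 (camera, adjusted p = 0.01583; adjusted p = 0.1551 with an estimated correlation). Among them Hr38, a nuclear receptor gene induced by neuronal activity, rose from 15.16 ± 1.686 to 196 ± 5.272 CPM, and the clock gene cyc fell from 38.56 ± 5.11 to 20.48 ± 1.69 CPM.

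Glycolysis genes rose in 13 of 14 cases, with a median log2 fold change of 2.43 (camera, adjusted p = 1.008e-10; adjusted p = 0.06482 with an estimated correlation). The list also holds genes that do not encode glycolytic enzymes, namely Gpdh, which encodes glycerol-3-phosphate dehydrogenase, and the mitochondrial carrier genes sesB and Mpc1. Gpdh rose by 4.84 ± 0.112 and the glycolytic gene Pfk by 4.13 ± 0.113 on the log2 scale (SE). The carrier gene sesB rose by 1.19, and Mpc1 was the member that did not pass (log2 fold change -0.033). Nuclear genes of oxidative phosphorylation rose in 49 of 66 cases and fell in 2 (median 0.6; camera, adjusted p = 1.286e-10; adjusted p = 0.3144 with an estimated correlation). Among them ND-75 rose from 214 ± 78.82 to 724.8 ± 34.94 CPM, and SdhB from 161.4 ± 17.69 to 562.7 ± 64.68 CPM. Their summed share of CPM went from 4.12% ± 0.266 to 5.81% ± 0.152, with the groups not overlapping (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Mitochondrially encoded genes rose in 6 of 10 cases without passing as a list (camera, adjusted p = 0.05138), although the list passed under 5 other settings (0.01438 without adult replicate 1) and in 2 fits with the filter applied anew (0.01 without the same library). Over all settings at the preset correlation its adjusted p ran up to 0.1649. In that list mt:Cyt-b went from 501.8 ± 69.2 to 946.9 ± 158.6 CPM. Vacuolar proton pump genes rose in 16 of 18 cases (camera, adjusted p = 1.423e-05; adjusted p = 0.1158 with an estimated correlation), Vha68-1 from 760 ± 32.46 to 1849 ± 54.01 CPM.

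Cytosolic ribosomal protein genes fell in 80 of 82 cases and rose in 0, with a median log2 fold change of -1.3 (camera, adjusted p = 2.041e-19; adjusted p = 0.2528 with an estimated correlation). Their share of CPM was 3.39% ± 0.315 in development and 1.37% ± 0.0642 in adult (SD, n = 3; exact permutation p = 0.1). RpL13A fell from 1132 ± 100.8 to 266.7 ± 17.72 CPM. All 31 tested proteasome genes fell, with a median of -1.43 (camera, adjusted p = 5.659e-11; adjusted p = 0.1299 with an estimated correlation). Prosalpha4 went from 289.4 ± 5.871 to 56.93 ± 1.765 CPM. Translation factors and tRNA ligases fell in 46 of 61 cases, 47 when adjusted over the list alone, and rose in 4 (camera, adjusted p = 1.667e-05; adjusted p = 0.08086 with an estimated correlation). The factor gene eIF-5A fell from 645.8 ± 81.3 to 90.6 ± 6.436 CPM. Spliceosome genes fell in 26 of 38 cases and rose in 2 (camera, adjusted p = 0.0002236; adjusted p = 0.08086 with an estimated correlation). In this list SmF fell by 2.72 ± 0.25 on the log2 scale. Mitochondrial ribosomal protein genes went the other way as a list, with 27 of 72 higher and 11 lower (median 0.21; camera, adjusted p = 0.01583; adjusted p = 0.6729 with an estimated correlation), a call that ended without development replicate 1 (adjusted p = 0.06706, or 0.08377 with the filter applied anew).

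**Figure D2:**
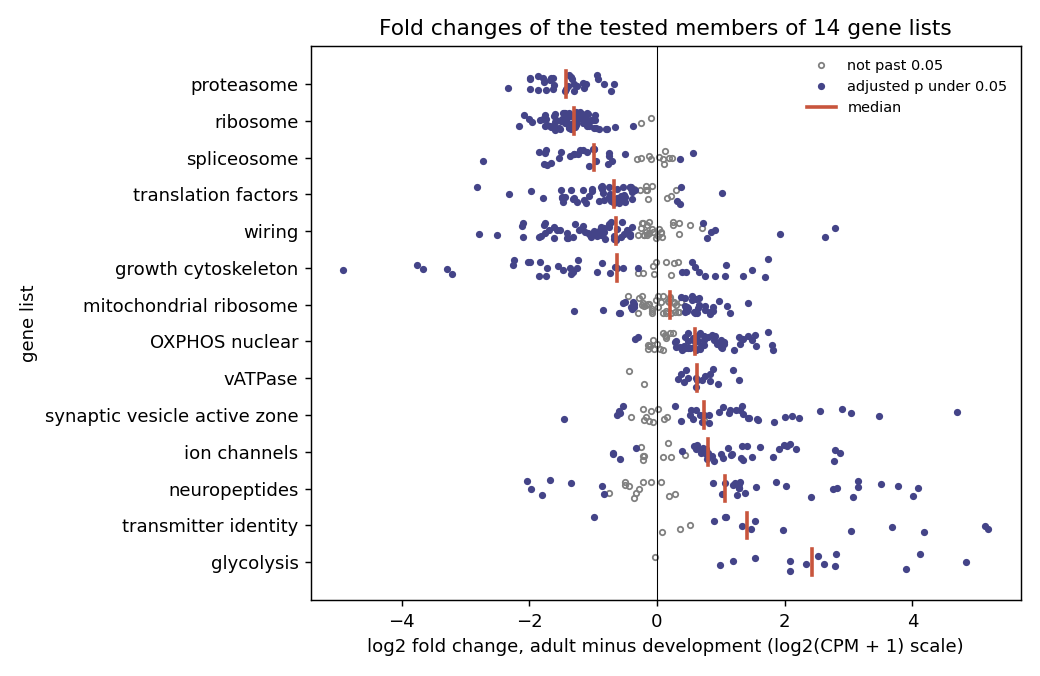
Log2 fold change, adult minus development on the log2(CPM + 1) scale, of every tested member of 14 gene lists, with filled points past an adjusted p of 0.05, open points not past it, and a bar at each list's median. Medians run from -1.43 for the proteasome to 2.43 for glycolysis.

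Heat shock and stress genes fell in 14 of 18 cases, 15 when adjusted over the list alone, and rose in 2 (median -1.33; camera, adjusted p = 0.0005725; adjusted p = 0.203 with an estimated correlation). Beside Hsp67Bc, the small heat shock gene Hsp23 fell from 3364 ± 351.4 to 246.3 ± 27.12 CPM and Hsp83 from 4986 ± 202.9 to 2599 ± 101.2 CPM. The co-chaperone gene stv rose from 82.02 ± 7.493 to 126.6 ± 16.42 CPM. Ecdysone response and temporal genes moved both ways, 8 of 29 higher and 12 lower (camera, adjusted p = 0.4586). Within that list the nuclear receptor genes Hr4 and Hr46 fell, by 7.13 ± 0.142 and 3.1 ± 0.191 on the log2 scale, while EcR, br and Eip93F did not pass the test, with log2 fold changes of 0.16, -0.21 and -0.22. The value of Hr46 is uncertain, since 61.79% of its exonic bases also belong to CG12912 and 58.01% to CG46321 on the same strand. EcR passed with median of ratios scaling (adjusted p = 0.02793) and with quantile normalization (0.03623), with up to 0.5349 under other settings. The RNA-binding protein genes Imp and Syp went from 16.43 ± 0.8971 to 27.62 ± 6.661 CPM and from 801.1 ± 78.37 to 426.6 ± 7.015 CPM, and both passed (limma, adjusted p = 0.009986 and 1.817e-06).

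Transcription factors of projection neuron types or lineages fell in 17 of 35 cases and rose in 5, 6 when adjusted over the list alone (camera, adjusted p = 0.2748). Of the lineage factors, acj6 had 169.2 ± 10.22 CPM in development and 146.4 ± 6.097 CPM in adult and did not pass (limma, adjusted p = 0.106), except with array weights (0.03521; up to 0.6606 under other settings). The factor gene vvl fell from 30.74 ± 6.173 to 17.03 ± 0.7217 CPM, and Oaz fell from 463.4 ± 31.42 to 296.5 ± 11.77 CPM. Mef2 rose from 12.12 ± 5.134 to 231.8 ± 10.15 CPM and fru from 163.1 ± 34.04 to 495.7 ± 27.43 CPM. The pan-neuronal gene elav had 230.7 ± 111 CPM in development and 209.5 ± 15.94 CPM in adult (limma, adjusted p = 0.8818), and without development replicate 1 its log2 fold change was 0.326 (adjusted p = 0.01112). Of its exonic bases 27.94% also belong to a noncoding gene on the same strand. Apoptosis genes fell in 6 of 9 cases and rose in 1 (camera, adjusted p = 0.1441), and passed as a list without a filter (0.02817; up to 0.2859 under the other settings). The caspase gene Dronc fell by 2.36 ± 0.217 on the log2 scale (SE) and the caspase gene Drice fell by 2.11 ± 0.143, while the inhibitor gene Diap2 rose by 1.86 ± 0.112.

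Markers of other cells moved in several directions. Photoreceptor markers rose in 7 of 8 cases and fell in 1 (median log2 fold change 2.83; camera, adjusted p = 0.0008654; adjusted p = 0.1158 with an estimated correlation). The most abundant was the phospholipase C gene norpA, at 280.7 ± 8.68 CPM in development and 922 ± 12.73 CPM in adult. Kenyon cell markers rose in 6 of 11 cases and fell in 1 (camera, adjusted p = 0.02064; adjusted p = 0.1582 with an estimated correlation). Mef2 and rut were higher and Fas2 lower, while mub, the most abundant, did not pass the test (limma, adjusted p = 0.1951). Glial markers rose in 7 of 17 cases and fell in 4 (camera, adjusted p = 0.1307). The glial gene repo stayed near 1 CPM in both groups, at 0.8508 ± 0.09066 and 1.081 ± 0.2658, while Gs2, a glutamine synthetase gene, rose from 50.88 ± 9.657 to 333.5 ± 67.35 CPM. Markers of dividing cells rose in 1 of 11 cases and fell in 5, 4 when adjusted over the list alone (camera, adjusted p = 0.376). Hemocyte markers rose in 2 of 6 and fell in 2 (camera, adjusted p = 0.472).

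Fat body genes rose in 6 of 13 cases and fell in 6 (camera, adjusted p = 0.6703), with a median of -0.45 where camera's direction was upward. With the filter applied anew they passed without development replicate 2 (camera, adjusted p = 0.02441) and replicate 3 (0.03777), with up to 0.8765 under other settings. Olfactory receptor neuron and antennal genes rose in 4 of 10 cases and fell in 3 (camera, adjusted p = 0.7079), with a mean of -0.19 where the median and camera were upward. Of 3 tested muscle markers 1 rose and 1 fell, and of 2 tested cuticle genes 1 rose and 1 fell, too few for a list test. Detoxification genes rose in 14 of 24 cases and fell in 8 (camera, adjusted p = 0.05887). They passed as a list with a variance model without a trend (0.03016) and without development replicate 3 (0.04011), with an adjusted p of up to 0.4837 under other settings, where its direction turned (the filter applied anew without adult replicate 1). GstS1 rose from 11.86 ± 1.968 to 92.37 ± 11.93 CPM and GstZ2 fell from 741 ± 59.01 to 90.09 ± 14.87 CPM. Immune genes rose in 1 of 5 cases (camera, adjusted p = 0.3257). Sex-linked and yolk genes rose in 4 of 7 cases and fell in 2 (camera, adjusted p = 0.09411). The dosage compensation RNA roX1 stood at 911.8 ± 117 and 1370 ± 31.74 CPM and roX2 at 450.1 ± 57.96 and 226.8 ± 26.99 CPM in development and adult. In 13 of the 14 classes of summed CPM the groups did not overlap, 10 higher and 3 lower in adult. Each of the 13 had an exact permutation p of 0.1 (0.1077 adjusted over the classes), so none could reach 0.05, and markers of dividing cells overlapped (exact permutation p = 0.3).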

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

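The 18 alternatives for genes, 17 for lists and 8 for shares were all chosen before the data were examined, but how genes were filtered when a library was left out was not. Those fits were first run with the filter applied anew to the libraries left. After their results had been seen, the tested genes were held fixed instead, and the values below are of that kind unless stated. The count of changed genes, 4439, lay within 1.5 times under 17 of the 18. Requiring an absolute log2 fold change of at least 1 gave 2145 genes, 916 higher and 1229 lower, as that threshold removes smaller changes. Leaving out each library in turn gave 4043 to 4500 genes (3932 to 4382 with the filter applied anew), and limma voom on the recovered reads gave 4436, of which 4390 were among the 4439. Median of ratios scaling moved the median log2 fold change from -0.153 to -0.008 and the share of rises among calls from 41.81% to 50.47%. Lists past the threshold numbered 18 to 21 with a library left out (16 to 22 with the filter applied anew) and 0 with an estimated correlation, 0 higher and 0 lower (the cause was not tested). In 13 of 14 classes the groups' shares did not overlap, and 13 to 14 did so with a library left out.

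Apart from the correlation, 3 lists lost their call under some setting and 3 gained one, those of mitochondrially encoded, apoptosis and detoxification genes. Of 144 named genes 10 lost and 5 gained their call. Adding the 7 members missed by letter case, an alternative chosen after the data were seen, changed 0 list calls (20 lists passed). With the filter applied anew, 5 lists lost and 2 gained their call. The mean then ran from -0.49 to 0.92 for detoxification genes, from -1.684 to 1.182 for fat body genes and from -1.158 to 0.776 for olfactory receptor neuron genes. For these 3 lists camera's direction turned downward without each adult library, where the filter drops genes found in adult alone. Directions turned only for lists and genes that had not passed. Without a filter camera's direction turned for immune, hemocyte and fat body genes, with means of 0.032, -0.117 and -0.714 against 0.549, 0.555 and -0.295 before, so that only the hemocyte mean changed sign. The dpr and DIP genes had 0.03 with median of ratios scaling and -0.151 to -0.078 with a library left out, where camera's direction turned while the mean did not. For elav the log2 fold change was 0.108 with median of ratios scaling, 0.074 with quantile normalization, 0.225 with array weights, and -0.226 to 0.326 with a library left out. It was -0.066 for brp with quantile normalization, and -0.043 to 0.149 for Ten-m with a library left out. The cause was not tested.

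Replicate numbers recur in both groups. Deviations from the group means correlated by -0.028, 0.042 and -0.011 between libraries of the same number, and by -0.043 to 0.041 between libraries of unlike numbers. No effect shared by equal numbers was thus detected. With 3 libraries per group this cannot exclude pairing, and the labels do not say whether equal numbers belong together. With the replicate block 4428 genes changed. Genes under 5 CPM in most libraries were not tested. In the shallowest library, at 18602628 reads, 1 read stood for 0.0538 CPM, so the filter rather than depth set the lowest level compared.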

Other observations

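A set of genes for protein folding and translocation in the endoplasmic reticulum, put together after their values were seen, was lower in adult throughout. All 18 tested members fell, with a median log2 fold change of -2.14 (camera, adjusted p = 3.014e-10; adjusted p = 0.006767 with an estimated correlation), a test that cannot be independent evidence, since the set was chosen for its fall. CaBP1 went from 597.7 ± 27.15 to 69.81 ± 7.641 CPM (SD, n = 3), Hsc70-3, the gene of the chaperone BiP, from 1419 ± 223.6 to 280.1 ± 15 CPM, and the calreticulin gene Calr from 1514 ± 61.48 to 328.5 ± 45.73 CPM. The 8 genes of the cytosolic chaperonin, chosen in the same way, all fell as well (median -1.64; camera, adjusted p = 2.5e-05; adjusted p = 0.04151 with an estimated correlation). Cct5 went from 433.3 ± 27.55 to 85.12 ± 7.421 CPM. The p values of these added sets were adjusted over the added sets alone. They cannot be compared with those of the 34 fixed lists tested, of which 0 passed with an estimated correlation.

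Other genes singled out after their values were seen include some with numbered symbols that the naming rule passed over. CG12643 had 1214 ± 136.8 CPM in development and 0.7742 ± 0.7017 CPM in adult, a log2 fold change of -9.48 ± 0.227 (SE; limma, adjusted p = 1.631e-12). CG17029 went from 0.4112 ± 0.4053 to 221.2 ± 4.462 CPM, and CG7582 from 1.171 ± 0.2656 to 208.1 ± 1.13 CPM. The glycogen phosphorylase gene GlyP rose from 30.85 ± 1.459 to 282.9 ± 19.87 CPM, the calcium-binding protein gene Cbp53E from 80.81 ± 3.187 to 1300 ± 34.63 CPM, and the noncoding RNA CR31451 from 806.3 ± 61.61 to 4814 ± 129.2 CPM. The innexin gene shakB, which encodes a gap junction protein, fell from 809.9 ± 80.52 to 139.6 ± 5.533 CPM. The most abundant gene row was the noncoding RNA noe in development, at 26720 ± 854.5 CPM, and Atpalpha, a sodium pump gene, in adult, at 46040 ± 2577 CPM.

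In what follows, the tests of scaling, of Ddc, of photoreceptors, of Proc and Dh44, of heat shock genes and of list counts over other splits were chosen after the results were seen, while those of gene length, of the spread of neuropeptide precursors and of gene counts over other splits were not. The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split was the 1 split with as many as 4439 changed genes, and the highest of the others gave 0. For lists at the preset correlation, the real split, with 20 lists, was likewise 1 of 10, but another split reached 17 lists with 0 changed genes, so counts of lists at that setting carry little weight. Every other split mixes both stages in each group. The stage difference then widens the spread within groups, so a low count of genes there was fixed in advance. Such splits also keep a part of the stage contrast, so neither count tests whether the grouping arose by chance.

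Ribosomal protein and proteasome genes were lower in adult, with a median log2 fold change of -1.32 over 113 genes. With each library's median log ratio set to 0 the median was still -1.17 (quartiles -1.46 and -0.97). That scaling shifts all genes nearly alike, moving the median of all tested genes from -0.153 to -0.008. It therefore shows a fall relative to the median gene, and cannot tell whether amounts per cell fell. These genes are short, with a median exon length of 974.5 bases against 2276 for the other tested genes, yet their difference from the 20 genes of nearest exon length had a median of -0.93 (quartiles -1.24 and -0.7), and nuclear genes of oxidative phosphorylation, at a median of 836 bases, had a median log2 fold change of 0.6. Length may therefore account for a part of the fall but not for all of it. Age, the difference that the design names, stays open and was not tested.

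Some transcripts known from other cells, such as Ddc, norpA and some neuropeptide precursors, were higher in adult. Dopaminergic or serotonergic neurons in the adult sorts were assumed, without a test, to bring ple and Trh in some proportion to Ddc. The summed rise of ple and Trh was 0.00449 of the rise of Ddc (0.00638 in the highest adult library). Other genes of such neurons did rise, the vesicular monoamine transporter gene Vmat from 9.331 ± 6.701 to 180.3 ± 107.7 CPM and the dopamine transporter gene DAT from 3.745 ± 1.294 to 12.9 ± 8.475 CPM. Only under that assumption do the values of ple and Trh argue against these neurons as the main source of the rise of Ddc. A small number of them is not excluded. Likewise, photoreceptors were assumed, without a test, to bring rhodopsin RNA along with norpA and rdgB, but the rise over 7 rhodopsin genes was 0.0459 of theirs (0.0522 in the highest library). Here too other genes of such cells rose, Arr2 from 0.2067 ± 0.2088 to 28.39 ± 1.312 CPM, trp from 0.6311 ± 0.597 to 10.68 ± 4.523 CPM, Arr1 from 0.2257 ± 0.3635 to 7.53 ± 1.42 CPM and Rh2 from 0 in all 3 libraries to 38.32 ± 6.956 CPM, so a small number of photoreceptors is not excluded. Rh2 made up nearly all of the rhodopsin rise, since the 7 genes together went from 5.929 ± 2.841 to 44.27 ± 5.035 CPM.

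Neuropeptide precursors gave another picture: their SD between adult libraries lay at a median percentile of 84 among 50 genes of nearest level (30 genes; permutation p = 1e-05, the smallest that 100000 random lists can give; 66 over 14 genes in development, permutation p = 0.1078), as with Mip, singled out for its spread, at 8.977, 3.724 and 194.4 CPM. For such precursors this is consistent with peptide-producing cells, or their free RNA, entering single adult sorts, in spite of the GFP gate, although differences between the animals of each sort stay open. The permutation p treats the 30 genes as independent, though they share the same adult libraries and may vary together, so it overstates the evidence. Entry into single sorts does not account for the rise of Proc, at 129.6, 183 and 136 CPM in the adult libraries, or of Dh44, at 36.36, 41.84 and 46.57 CPM, since the lowest adult library still held 0.859 of the mean rise. Of the 30 precursors 21 were higher in every adult library than in any of development, where chance gives 5%. These 30 were taken by a mean of at least 2 CPM in adult, which favours rises. Among all tested genes the groups did not overlap, in either direction, for 68.99%. The count of 21 is therefore no test of the precursors. The source of Vmat, DAT, Gad1, Arr2, trp and Arr1 and of the low rhodopsin signal, 44.27 ± 5.035 CPM summed in adult, stays open, as does a change with age in the sorted neurons themselves.

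Small heat shock genes were far higher in development, at 15590 ± 1505 summed CPM against 684.6 ± 101.1 in adult (6 genes; SD, n = 3). Heat or dissociation stress in the developmental sorts was assumed, without a test, to raise the Hsp70 genes and Hsp68 at least as much. Their sum over 7 genes was 347.1 ± 14.2 CPM in development and 209.6 ± 12.47 CPM in adult. Hsp68 went from a mean of 114.5 to 53.5 CPM and Hsp70Ab from 43.53 to 13.59 CPM. Both passed the test, as did the falls of Hsp70Ba and Hsp70Bc. Hsp70Bb, the most abundant, had 164.2 and 133.8 CPM and did not pass (limma, adjusted p = 0.06199). The log2 change of the Hsp70 genes and Hsp68 lay 3.79 ± 0.15 (SE) above that of the small heat shock genes. Only under that assumption does stress fail to account for the whole fall of the small heat shock genes. Some stress in the developmental sorts stays open, since Hsp70 genes and Hsp68 were also higher there. Reads shared between near-identical Hsp70 copies may lower the level of those genes in both groups. Age, the difference that the design names, stays open and was not tested.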
